A study of Homo sapiens with 2 samples.

How the data were processed

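Droplet single-cell RNA-seq was performed with a 5′ kit on T cells from lung, brain and pleural fluid of 4 patients with lung cancer. Live CD45+ CD3+ cells were sorted from thawed suspensions, tagged with hashtag antibodies and mixed. The data form 1 group of 2 libraries, called library 1 and library 2 after the labels' numbers. Per the labels, the libraries received 108e6 reads on average. Nothing in the labels says that the libraries came from separate donors or sorts, so p-values measure only the spread between these 2 libraries, which may be technical. No map from cells to patients or tissues was used here, and patients and tissues were therefore not compared.

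The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. Per the file headers, they came from Cell Ranger 3.1.0 and list 33538 human genes of GRCh38 beside 31053 mouse genes of mm10. The submitters' processing notes also name Seurat 3.0.0, GRCh38 and hg38. All 64591 features were of the gene expression type, so CD39 was read from ENTPD1 RNA and not from antibody counts. Whether counting used strand is not given in the sources used here. Mouse genes were kept out of every comparison, and 130 human genes (those on chromosome Y, XIST and TSIX) were removed at loading. Gene positions were taken from GENCODE release 29 on GRCh38, matched by Ensembl identifier.

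Library 1 held 1367 barcodes with 6297521 human UMIs, and library 2 held 1002 barcodes with 3405296. Barcodes with under 200 human genes were removed (51 and 53), as were those with 15% or more mitochondrial UMIs (2 and 8). Scrublet, run per library, called 10 and 11 doublets (0.761% and 1.17%), which were removed. This left 1304 and 930 cells with medians of 3905.5 and 2894.0 UMIs per cell. The summed counts of the libraries differed by more than sampling noise (chi-square of 5.73 per degree of freedom over 12251 genes), so the libraries were not merged. This test takes UMIs as independent and cannot tell 2 samples from 2 lanes of 1 pool; log2 CPM correlated at 0.988 between the libraries.

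Cells were classed by UMIs alone. A CD8 T cell carried at least 1 UMI of CD3D, CD3E, CD3G or TRAC, at least 1 of CD8A or CD8B, and 0 of CD4 and FOXP3. A CD4 non-regulatory T cell met the same T cell requirement and carried at least 1 UMI of CD4 or CD40LG and 0 of CD8A, CD8B and FOXP3, and a regulatory T cell passed the CD4 gate with at least 1 FOXP3 UMI. CD39-positive cells carried at least 1 ENTPD1 UMI. Because 1 UMI decides the class, deeper cells are more often positive, and negative cells include expressing cells in which ENTPD1 was missed. Clusters were built in scanpy 1.11.5 from 1500 variable genes without ENTPD1 and without receptor segments, 20 principal components, 15 neighbours and Leiden resolution 1.0, with no integration of the libraries.

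Counts were summed per library and class and tested with the edgeR 4.0.16 quasi-likelihood F test (R 4.3.3, TMM, filterByExpr, library as a block, Benjamini-Hochberg adjusted p under 0.05). The SE given beside a fold change is the log2 fold change divided by the square root of F. With 2 classes in 2 libraries, 1 residual degree of freedom remained per gene, and the test draws on the spread across genes. The library number served as the block because both classes came from the same library. The block does not cover patient or tissue, which are mixed within each library. Differences between classes may therefore partly be differences between patients or tissues. For 20 gene lists (242 genes), camera of limma 3.58.1 was run with a preset correlation of 0.01, beside fry and camera with an estimated correlation. The last 2 draw on the 1 residual degree of freedom and could hardly call a list here. A list that misses their threshold is therefore neither supported nor contradicted by them. Levels are given as UMIs per 1000000 summed UMIs (CPM). Shares carry 95% Wilson intervals, and a share of 0 carries the limit that 3 counts would give; both cover counting error only.

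The named genes were fixed by rule before the data were examined. For CD8 cells the rule takes the 12 highest and 12 lowest log2 fold changes among genes past the threshold with the same sign in both libraries and at least 20 UMIs, plus up to 4 members of each list by smallest p. For CD4 cells and for the difference between lineages it takes 6 each way. ENTPD1 was left out of counts, and receptor segments, HLA-DRB3/4/5, mitochondrial and ribosomal protein genes and genes without a symbol were left out of names. The comparisons, lists and most alternatives were likewise chosen before the data were examined. The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no block, no filter on low counts, doublets kept, all barcodes, and CD8 cells taken by cluster. Others were cycling cells removed, each library left out, cells thinned to 2000 UMIs, and negative cells matched 3 to 1 by UMI depth. Removing cells with TRBV19, staying within 1 cluster, and an estimated correlation in depth-matched cells and without TRBV19 cells, were added after seeing the data.

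On simulated data with the real depths (7625 genes in the CD8 split), 53 of 100 genes changed 2-fold and 79 of 100 changed 4-fold were recovered, with 5 false calls among 137. In the CD4 split (3706 genes) the numbers were 0 and 3 of 100, and for the difference between lineages (6504 genes) 8 and 19 of 100, with 7 false calls among 34. For regulatory against CD4 cells (7881 genes) 4 and 46 of 100 were recovered, and for CD8 against CD4 cells (7773 genes) 57 and 99. In a simulation over 7631 genes, camera found the 1 changed list with 0 false calls. All simulations drew genes independently, with a biological coefficient of variation of 0.1, random lists and no selection of cells by 1 UMI. They therefore do not show how often false calls arise in the real splits or lists.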

Results

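The study asked whether CD39, the ectonucleotidase encoded by ENTPD1, marks tumour-reactive CD8 T cells in lung cancer. The data are UMI counts of sorted T cells in 2 libraries of mixed lung, brain and pleural fluid cells. In library 1, 640 of 1304 cells (49.1%, Wilson interval 46.4 to 51.8) passed the CD8 gate, and in library 2, 365 of 930 (39.2%, 36.2 to 42.4). The CD4 non-regulatory gate held 194 cells (14.9%, 13.05 to 16.91) and 115 cells (12.4%, 10.4 to 14.6). The regulatory gate held 11 cells (0.844%, 0.472 to 1.504) and 7 cells (0.753%, 0.365 to 1.55). The cells left over entered none of the main comparisons. T cells without a CD8A, CD8B, CD4 or CD40LG UMI numbered 424 (32.5%) and 365 (39.2%), 9 and 1 of them with an ENTPD1 UMI. T cells with CD8A or CD8B beside CD4 or FOXP3 numbered 29 and 16. They were deep (medians of 10906.0 and 9224.0 UMIs), and 8 (27.6%) and 4 (25%) carried an ENTPD1 UMI. No UMI of the T cell genes was found in 6 and 62 cells.

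Unsupervised clustering gave clusters numbered 0 to 12. Cluster 9 was cycling-like, led by UBE2C, MKI67 and TOP2A. Cluster 12 was regulatory T-like, with FOXP3 and IL2RA among its 10 leading genes, and cluster 6 was circulating effector T-like, led by FGFBP2 and FCGR3A. The other clusters are given by number. Cluster 7 was led by HMOX1, HLA-DQA1 and VCAM1, with CXCL13 and DUSP4 in its leading 10, and cluster 2 by C1orf21, EOMES and ITM2C. Cluster 7 made up 10.6% (9.03 to 12.4) of library 1 and 9.78% (8.04 to 11.9) of library 2. Cluster 8 made up 6.37% (5.16 to 7.82) and 20.2% (17.8 to 22.9). Its cells were shallower in library 2 (median 1876.0 UMIs) than in library 1 (4286.0), and the libraries were not integrated.

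ENTPD1 was detected more in CD8 T cells than in CD4 non-regulatory T cells. The gene (ENSG00000138185) lies on the plus strand of chromosome 10 from 95711779 to 95869695 in GRCh38 and is protein coding; the antisense gene ENTPD1-AS1 overlaps it. Of CD8 cells, 53 of 640 (8.28%, 6.39 to 10.7) carried an ENTPD1 UMI in library 1 and 17 of 365 (4.66%, 2.93 to 7.33) in library 2. Of CD4 non-regulatory cells, 2 of 194 (1.03%, 0.283 to 3.68) and 2 of 115 (1.74%, 0.478 to 6.12) did, although they were deeper (medians of 4503.0 and 4702.0 UMIs against 3480.5 and 2994.0). In summed counts ENTPD1 was 7.34-fold higher in CD8 than in CD4 non-regulatory cells (log2 fold change 2.88, SE 0.65, n = 2 libraries, edgeR adjusted p = 2.33e-04), from 100 and 4 UMIs.

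The call on ENTPD1 ended with DESeq2 at nearly the same size (log2 fold change 2.92, adjusted p = 0.11). Thinned to 2000 UMIs per cell, the shares in CD8 cells were 3.81% (22 of 577, 2.53 to 5.71) and 2.11% (5 of 237, 0.904 to 4.84), against 0.909% (1 of 110) and 1.75% (1 of 57) in CD4 cells. The intervals of the thinned CD4 shares (0.161 to 4.97 and 0.310 to 9.29) overlap those of the CD8 shares in both libraries, as the unthinned intervals do in library 2. Thinning left out 51 and 317 shallower cells.

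Regulatory T cells, a population known to express CD39, were too few to compare. They held 2 ENTPD1 UMIs in 2 of 11 cells of library 1 and 0 in 7 cells of library 2, which allows a share of up to 42.9%. The log2 fold change over CD4 non-regulatory cells was 2.58 (SE 1.64, edgeR adjusted p = 0.62) and was not past the threshold. In regulatory T-like cluster 12, which takes cells of any gate, 6 of 26 cells (23.1%, 11.03 to 42.1) carried an ENTPD1 UMI. FOXP3, which defines the class, and IL2RA (log2 fold change 2.61, SE 0.65, edgeR adjusted p = 0.011) were higher in the regulatory gate than in CD4 non-regulatory cells.

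Among CD8 T cells, ENTPD1 detection was concentrated in some clusters. In both libraries together, 37 of 178 CD8 cells of cluster 7 (20.8%, 15.5 to 27.3) were positive, but the libraries differed: 31 of 115 in library 1 (27.0%, 19.7 to 35.7) and 6 of 63 in library 2 (9.52%, 4.44 to 19.3). Of the pooled cells, 7 of 35 were positive in cycling-like cluster 9 (20%, 10.04 to 35.89). In cluster 11, led by KLRC1, GNLY and KIR2DL4, 7 of 42 (16.7%, 8.32 to 30.6) were positive, and in cluster 0, led by TMIGD2, LRRN3 and ASB2, 13 of 95 (13.7%, 8.17 to 22.0). In library 2 the shares of clusters 0 (4 of 33), 9 (3 of 11) and 11 (2 of 6) lay above that of cluster 7, on few cells. In cluster 2, 0 of 250 cells were positive, which allows a detected share of up to 1.20%, and in circulating effector T-like cluster 6, 0 of 62 (up to 4.84%). These limits bound detection at this depth and not the share of expressing cells, and background ENTPD1 UMIs were not measured. Per summed UMIs, ENTPD1 stood at 61.6 CPM in cluster 0, 57.0 in cluster 11, 43.5 in cluster 7 and 35.7 in cluster 9. In the same order the values were 71.1, 49.4, 47.9 and 25.5 in library 1. In library 2 they were 42.0, 105.9, 33.0 and 59.8, so the ranking differed. Median depths were 5488.0 UMIs in cluster 7, 9520.0 in cluster 9, 2909.0 in cluster 0 and 2982.0 in cluster 2. Thinned to 2000 UMIs, cluster 7 had 15 positive cells of 170 (8.82%), cluster 0 6 of 75, cluster 2 0 of 190, and clusters 9 and 11 had 1 of 39 each (2.56%). By library, thinned cluster 7 had 13 of 115 (11.3%) and 2 of 55 (3.64%). Cluster 0 had 4 of 53 (7.55%) and 2 of 22 (9.09%).

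**Figure D1:**
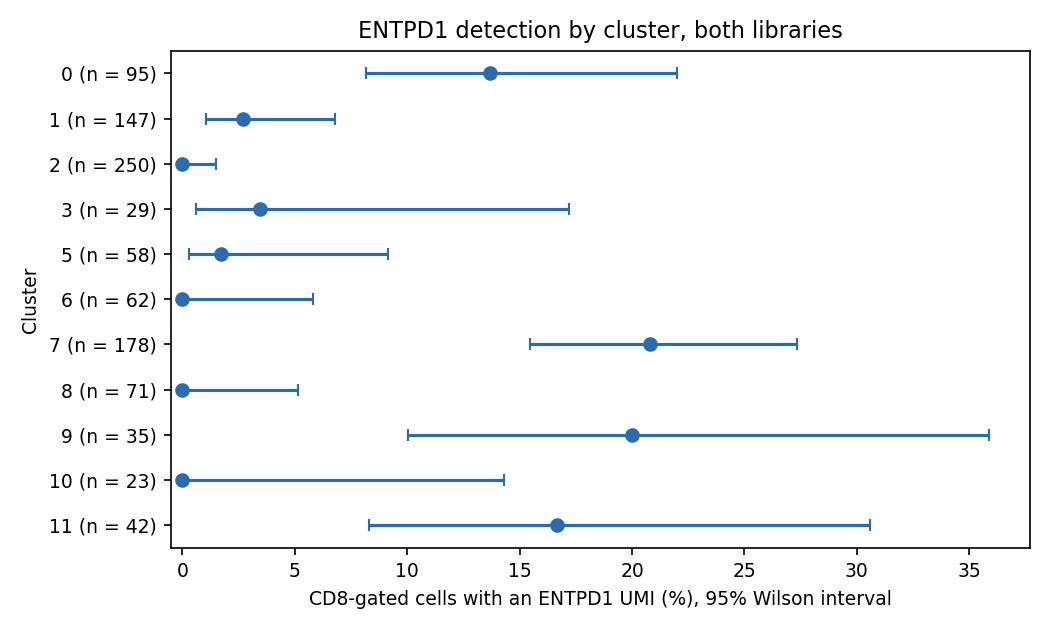
Percent of CD8-gated cells with an ENTPD1 UMI (x axis) in each cluster with at least 20 such cells (y axis, with the number of cells), both libraries together; points are shares and bars 95% Wilson intervals. Cluster 7 stands at 20.8% (27.0% in library 1 and 9.52% in library 2) and cluster 2 at 0 of 250 cells.

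CD39-positive CD8 T cells carried more RNA than CD39-negative CD8 T cells for some genes of antigen presentation and tumour reactivity, and less for some genes of recirculation and circulating effectors. HLA-DRA, the alpha chain of HLA-DR, rose from 340.7 and 306 CPM in negative cells to 1295 and 895 in positive cells (log2 fold change 1.67, SE 0.15, n = 2 libraries, adjusted p = 2.76e-08). VCAM1, an adhesion molecule, rose by 1.77 on the log2 scale (SE 0.19, adjusted p = 2.79e-07), and CXCL13, a chemokine that attracts B cells, by 1.25 (SE 0.14, adjusted p = 1.29e-06). FGFBP2, a marker of circulating cytotoxic cells, was lower (log2 fold change -2.47, SE 0.46, adjusted p = 1.35e-03), as was the interleukin-7 receptor gene IL7R (log2 fold change -0.75, SE 0.15, adjusted p = 3.01e-03).

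Of 7701 genes tested with edgeR, 118 were higher and 64 lower in the 70 CD39-positive CD8 cells. Patients and tissues could not be separated from these classes. The same sign in both libraries was seen for 181 of the 182, which choosing genes on these 2 libraries favours by itself. The called genes included 20 T cell receptor segments, 2 higher and 18 lower, and 7 ribosomal protein genes, which were lower. Positive cells were deeper, with medians of 6257.0 against 3417.0 UMIs in library 1 and 3549.0 against 2903.5 in library 2. Against depth-matched negative cells (159 and 51), edgeR called 0 genes (286 at an unadjusted p under 0.05; DESeq2 called 0, with 25). Matching balanced median UMIs (6257.0 against 6294.0, and 3549.0 against 3555.0) but not every measure of depth. Median genes were 2475.0 against 2068.0 in library 1. In library 2, 17 positive cells held 153261 UMIs and 51 matched cells 318576, fewer per cell. The matched comparison reuses all positive cells and some of the negative cells that gave the calls. Of the 149 called genes testable there, 147 kept their direction, which is not independent support. Their median signed log2 fold change went from 1.10 to 0.58. HLA-DRA went from 1.67 to 0.61, CXCL13 from 1.25 to 0.25, HMOX1 from 1.23 to 0.34 and VCAM1 from 1.77 to 0.97. DESeq2 on all cells called 45 genes, 22 higher and 23 lower. Cluster 7 held 37 of the 70 positive CD8 cells; within it edgeR called 0 genes (175 at an unadjusted p under 0.05; DESeq2 0, with 7), the median went from 1.00 to 0.22, and HMOX1, RGS1 and IL7R changed sign. Direction was kept by 95 of 127 genes there, among them CXCL13 (log2 0.64), HLA-DRA (0.46) and CCL5 (-0.60). Cluster 7 is led by some of the called genes, which by itself can make differences inside it smaller. Library 2 gave 6 positive cells in it.

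The highest fold changes belonged to SESTD1 (log2 2.83), AKAP2 (2.72), KIF20A (2.71), CCNB1 (2.46), ENC1 (2.35), CDC20 (2.27), GNA15 (2.23), KIF23 (2.12), RAB31 (2.12), BTNL8 (2.08), PLEKHG1 (2.07) and TOX2 (2.05). KIF20A, CCNB1, CDC20 and KIF23 are cell division genes, and TOX2 is a transcription factor related to TOX. Among the lowest were FGFBP2, KLF3 (log2 -2.17), ITGA5 (-2.05), MYC (-1.96), CISH (-1.92), KLRG1 (-1.92), SATB1 (-1.80), MPZL3 (-1.70) and C1orf21 (-1.63). TSC1, TYROBP and DKK3 were lower still, on 1, 2 and 3 UMIs in positive cells. Their ratios of positive to negative cells were 0.0940 (exact binomial interval 0.00235 to 0.541), 0.110 (0.0131 to 0.405) and 0.165 (0.0335 to 0.492). CD8A (log2 -0.34, adjusted p = 0.33) and CD8B (-0.33, adjusted p = 0.35), used to gate both classes, did not pass.

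**Figure D2:**
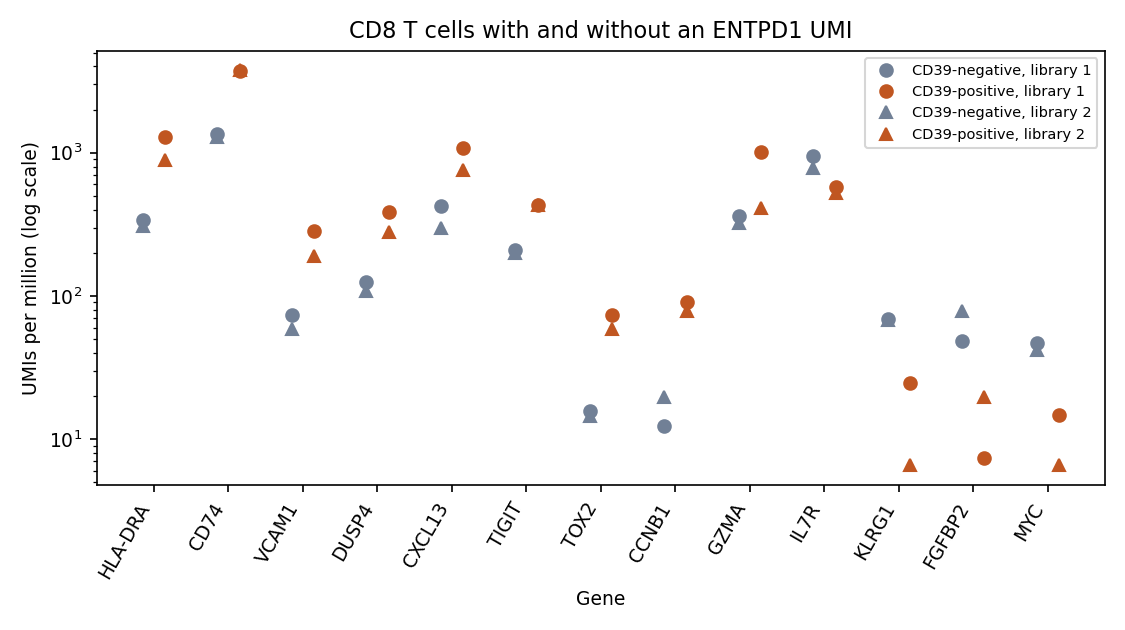
CPM (y axis, log scale) of 13 genes (x axis) in summed CD8 T cells without (grey) and with (orange) an ENTPD1 UMI; circles are library 1 and triangles library 2. HLA-DRA is at 1295 and 895 in positive cells against 340.7 and 306 in negative cells, and KLRG1 at 24.4 and 6.53 against 68.7 and 67.6.

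Genes of activation and MHC class II rose as a list: 5 of 7 tested members rose, 0 fell and 2 did not pass (6 higher when adjusted over the list alone; camera adjusted p = 1.13e-14, adjusted p = 0.53 with an estimated correlation). Besides HLA-DRA, these were CD74, the class II invariant chain (log2 1.41), HLA-DMA (1.17), HLA-DPB1 (1.10) and HLA-DPA1 (0.96). HLA genes are similar in sequence, and reads shared between them leave their single values uncertain. Transcripts of B cells, which carry class II genes, stood higher in positive cells of library 1 for each gene given next. In library 2 CD79A and MZB1 stood higher and MS4A1 and CD79B lower. CD79A stood at 9.77 and 13.1 CPM in positive cells against 3.55 and 5.99, MS4A1 at 24.4 and 6.53 against 3.16 and 8.56, CD79B at 29.3 and 6.53 against 11.1 and 17.1, MZB1 at 2.44 and 13.1 against 1.97 and 0.856, and BANK1 at 7.33 and 0 against 0 and 0. All but CD79B had too few UMIs to be tested, and CD79B did not pass (log2 0.68, SE 0.54). Whether RNA of B cells, or of other cells that carry class II genes, added to the rise was not tested.

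Of 13 tested tumour-reactive CD8 genes, 5 rose (8 adjusted over the list alone): VCAM1, CXCL13, the phosphatase gene DUSP4 (log2 1.45), heme oxygenase HMOX1 (1.23) and LAYN (1.15). The list's camera adjusted p was 9.29e-11 (adjusted p = 0.53 with an estimated correlation). Of 14 checkpoint and exhaustion genes, 3 rose (6 adjusted over the list alone): TOX2, the inhibitory receptor gene TIGIT (log2 0.99) and the transcription factor gene TOX (0.97); camera adjusted p = 3.74e-06, adjusted p = 0.53 with an estimated correlation. HAVCR2 (log2 1.02, SE 0.32, adjusted p = 0.095), which encodes TIM-3, did not pass, nor did CTLA4 (1.20, SE 0.41, adjusted p = 0.15), PDCD1 (0.28, SE 0.52) or LAG3 (-0.72, SE 0.43).

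Of 14 naive, memory and recirculation genes, 4 fell (7 adjusted over the list alone): IL7R, MYC, KLF3 and SATB1 (camera adjusted p = 1.34e-05, adjusted p = 0.53 with an estimated correlation). TCF7 did not pass (log2 0.02, SE 0.19). Of 8 circulating effector genes, 3 fell (4 adjusted over the list alone): FGFBP2, KLRG1 and C1orf21 (camera adjusted p = 4.87e-05, adjusted p = 0.53 with an estimated correlation). Of 15 cytotoxic genes, GZMA rose (log2 0.96), NKG7 (-0.69) and CCL5 (-0.62) fell, and the list did not pass (camera adjusted p = 0.27; 3 higher and 4 lower adjusted over the list alone; without TRBV19 cells it passed as higher, adjusted p = 3.24e-03, adjusted p = 0.43 with an estimated correlation). GZMA went from 361.7 to 1006.3 CPM in library 1 but only from 320.9 to 411.6 in library 2. Without TRBV19 cells, NKG7 stood at -0.08 and CCL5 at 0.06 (edgeR adjusted p = 0.96 for each), and GZMA at 1.39 (0.015).

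Of 19 proliferation genes, 6 rose (11 adjusted over the list alone), among them CCNB1, UBE2C (log2 1.495), CENPF (1.20) and MCM5 (1.15). The camera adjusted p was 7.72e-07 (adjusted p = 0.53 with an estimated correlation), and against depth-matched cells the call ended, with a median log2 fold change of -0.13 instead of 0.67. Several members rose mostly in library 2, on 17 positive cells. MKI67 went from 99.1 to 129.5 CPM in library 1 and from 71.0 to 313.6 in library 2. STMN1 (485.6 to 476.3, and 229.3 to 770.9) and TYMS (90.8 to 53.7, and 35.1 to 182.9) rose only in library 2. CCNB1 and MCM5 rose more in library 1. Of 12 interferon response genes, 1 rose, OAS1 (log2 1.31; 5 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.51e-04, adjusted p = 0.53 with an estimated correlation). This list also lost its call in depth-matched cells (adjusted p = 0.21).

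Follicular helper genes had 2 of 5 higher, CXCL13 and TOX2 (2 adjusted over the list alone; camera adjusted p = 8.95e-03). Regulatory T genes had 0 of 4 past the threshold (1 higher adjusted over the list alone; camera adjusted p = 0.042). The myeloid list rested on AIF1, its 1 tested gene (log2 1.34, adjusted p = 0.040; camera adjusted p = 0.029), while LYZ, CD14, S100A9 and FCER1G had 0 UMIs in positive cells and CD68 stood at 4.89 and 13.1 CPM against 3.95 and 5.99. For these 3 lists the adjusted p was 0.53 with an estimated correlation, and their calls ended in depth-matched cells (adjusted p = 0.24, 0.052 and 0.31), with medians going from 0.28 to 0.25, 0.36 to 0.37 and 1.34 to 0.58.

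Against depth-matched cells 5 lists kept their call at camera with the preset correlation: activation and MHC class II (median log2 0.53, adjusted p = 1.78e-06), tumour-reactive CD8 (0.27, 1.09e-03), checkpoint and exhaustion (0.34, 6.47e-03), naive, memory and recirculation (-0.61, 7.58e-07) and circulating effector genes (-1.15, 0.0125). Tissue residency (0.24, 0.0125) and natural killer and innate genes (1.55, 4.13e-05), which were not called against all negative cells, passed there as higher. The latter list held only KLRC1, XCL1 and XCL2 there, without TYROBP. With an estimated correlation, run on depth-matched cells after seeing the data, all 7 of these lists had adjusted p = 0.63. That test has 1 residual degree of freedom and could hardly call a list. Positive cells were not fully matched in depth, so depth may still bear on the calls above.

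The other lists did not pass camera against all negative cells. Tissue residency had 1 of 13 higher (RGS1, log2 0.90), GZMK memory 3 of 9 higher (CD74, SH2D1A and GZMK) and 1 lower (KLRG1), and oxidative phosphorylation 1 of 10 higher (COX5A, log2 0.57). Dissociation stress had 1 of 9 lower (IER2, log2 -0.87), and natural killer and innate genes 2 of 4 higher (XCL1, with opposite signs in the 2 libraries, and XCL2) and 1 lower (TYROBP). Glycolysis (9 genes), MAIT (2), B and plasma (1) and epithelial and stromal genes (1) had 0 past the threshold. Adjusted over the list alone, the counts higher and lower were 1 and 1 for tissue residency, 3 and 1 for GZMK memory, 1 and 0 for oxidative phosphorylation, and 0 and 2 for dissociation stress. They were 2 and 1 for natural killer, 1 and 1 for glycolysis, 0 and 0 for MAIT and for B and plasma, and 1 and 0 for epithelial and stromal genes. Median and mean log2 fold change differed in sign for tissue residency (0.01 and -0.04), glycolysis (0.04 and -0.03), natural killer (0.54 and -0.29) and no other list.

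**Figure D3:**
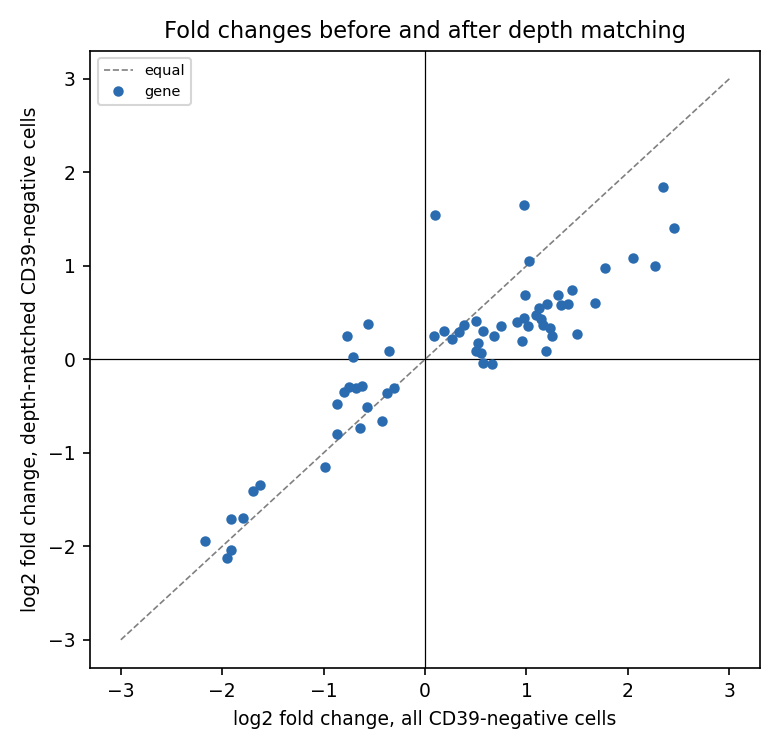
Log2 fold change of 64 named or listed genes in CD39-positive CD8 cells against all CD39-negative cells (x axis) and against depth-matched ones (y axis); each point is a gene and the dashed line marks equal values. For 54 of the 64 genes the matched value lies nearer to 0.

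CD39-positive CD4 non-regulatory T cells numbered 4, with 6444 and 21966 summed UMIs in the 2 libraries, and served as the reference for the CD8 split. CEP170 was higher in them (log2 3.61, SE 1.06, adjusted p = 0.044), and IL7R (-1.98), NACA (-1.49), VIM (-1.48), TMSB4X (-1.41) and EEF1A1 (-1.27) were lower. Of 3678 genes tested with edgeR, 5 were higher and 52 lower, 42 of them ribosomal protein genes. The median of all genes stood at -0.61 with TMM scaling, -0.44 with DESeq2 size factors and 0.04 with none, so the size of these decreases depends on the scaling. No gene passed against depth-matched cells (0 called by edgeR among 249 genes, 12 at an unadjusted p under 0.05). All these values rest on 4 positive cells, and values per cell were not examined.

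The CD39 change differed between CD8 and CD4 cells for 260 of 6564 genes in edgeR's interaction test, 210 with a higher value in CD8 cells and 50 with a lower one. ATP5F1A, SH2D1A, MZT2B, CACYBP, HSPD1 and RCAN3 had 0 UMIs in CD39-positive CD4 cells, a class of 28410 UMIs, and 342, 155, 372, 260, 257 and 221 in CD39-negative ones, a class of 1477393. At the rate of the negative cells 6.58, 2.98, 7.15, 5.00, 4.94 and 4.25 would be found. HMOX1 had 215 UMIs in CD39-positive CD4 cells, all in library 2, against 14 in CD39-negative ones, and TYROBP 8 against 4. Of the 2 positive CD4-gated cells of library 2, 1 lay in cluster 7, which HMOX1 leads. In that cluster 5 myeloid markers had a mean log2 ratio of 1.00 to all other cells, with 0 of them detected in 10% of its cells. Whether the positive CD4-gated cells were single T cells or held RNA of another cell type was not tested. With DESeq2 size factors the split was 81 higher and 67 lower, and with DESeq2 91 and 7. The median of all genes stood at 1.03 on the log2 scale with TMM, 0.58 with DESeq2 size factors and 0.15 with no scaling. The number of called genes and the excess of higher ones therefore depend on the scaling.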

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

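The tests on mouse-gene UMIs were chosen only after those UMIs had been seen, and removing TRBV19 cells was chosen after the data were seen but before its result. The test of the tumour-reactive list was written after the call counts of the same 100 splits were known and before the list medians were.

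The interaction test of edgeR called 260 genes for a CD39 change that differed between CD8 and CD4 cells. The median of all tested genes stood at 1.03 on the log2 scale with TMM and at 0.15 with no scaling. The count and its split into higher and lower therefore depend on the scaling. The UMIs in CD39-positive CD4 cells were 0 for ATP5F1A, SH2D1A, MZT2B, CACYBP, HSPD1 and RCAN3. They were 7 for ZEB2, 4 for YBX3, 8 for TYROBP, 2 for KLRC3, 215 for HMOX1 and 26 for ETS2, all of them in library 2. These values rest on 4 CD4-gated cells, and whether each was a single T cell was not tested.

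Genes changed in CD39-positive CD8 T cells were weighed first. Of 100 splits of the same CD8 cells by another gene detected in a like number of cells, 13 called at least as many genes as the 182 of the ENTPD1 split (median 35.5, highest 793), so a count of this size is not particular to ENTPD1. The UMI depth of positive cells stays open, also because matching in library 2 left positive cells with more UMIs per cell. The 200 genes with the largest differences in library 1 had a median signed log2 difference of 0.27 in depth-matched cells of library 2, which 4.7% of 1000 random sets reached (Wilson interval 3.55 to 6.19). The written bound was 5%, which 4.7 meets by itself and its interval does not. Reading it by the interval, and so leaving depth open, was decided after 4.7 had been seen; by the point value alone depth would have been excluded. The reverse direction was not in the written test either: chosen in library 2 and tested in library 1, the median was 0.02, and 39.3% of random sets reached it. Without cells carrying TRBV19, the called genes kept a median signed log2 fold change of 0.97 of 1.13, but these genes were chosen on overlapping cells, only 35 of the 182 stayed called, and the higher calls went from 118 to 23. VCAM1 (log2 2.48, adjusted p = 2.22e-03), HLA-DRA (1.93, adjusted p = 1.99e-03) and CXCL13 (1.64, adjusted p = 1.36e-03) passed again in the remaining 29 and 10 positive cells. This argues against the cells with a TRBV19 UMI as the whole cause; clone cells in which TRBV19 was missed were not removed. The proliferation list lost its call without them (median from 0.67 to 0.15), and a clone behind part of the higher genes stays open.

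The tumour-reactive CD8 list had a median log2 fold change of 0.67 in the ENTPD1 split. Of the 100 splits by other genes, 6 raised it as far (median 0.29, highest 0.91), just enough to meet the written bound. By that bound a rise of this size is not particular to ENTPD1, though most splits gave a smaller one. Unlike the depth test, this count was read without an interval. The study's groups offer no further contrast, and no biological explanation was tested.

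Mouse-gene UMIs made up 1.03% of library 1 and 2.35% of library 2, and 50 and 20 barcodes held more mouse than human UMIs, in data that no comparison used. In human-majority barcodes, Gm42418 and Lars2 held 99.4% and 99.6% of the mouse-gene UMIs, consistent with human reads that align to a ribosomal repeat. The mouse-majority barcodes were shallow (medians of 25 and 30 UMIs), and 12 of the 20 in library 2 (60%) were also in library 1, against 0.204% of human-majority barcodes, consistent with barcodes of another library sequenced alongside. No mouse-majority barcode (0 and 0) was among the cells used, and no biological explanation was tested.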

How the results depend on the processing

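The settings without TRBV19 cells and within cluster 7, and the estimated correlation in depth-matched cells and without TRBV19 cells, were chosen after seeing the data. The count of 182 genes in CD39-positive CD8 cells moved to 45 with DESeq2, 106 with DESeq2 size factors, 89 with doublets kept, 103 with all barcodes, 119 without cycling cells and 85 without TRBV19 cells (23 higher and 62 lower, 35 shared). It moved to 4 in thinned cells (247 at an unadjusted p under 0.05; 112 of 125 genes kept their direction, median from 1.00 to 0.86), to 0 against depth-matched cells and to 0 within cluster 7 (edgeR, 175 at an unadjusted p under 0.05; DESeq2 0, with 7). The first 4 settings gave the 182 genes the same direction, with a median signed log2 fold change between 1.32 and 1.33 against 1.31. The weight edgeR gives to the spread across genes, its prior degrees of freedom, was 28.1 in the main fit. It was 13.4 with DESeq2 size factors, 11.1 with doublets kept and 12.9 with all barcodes. A lower value makes calls harder at the same fold change. Without the replicate block it was 29.6, and the count was lower there too. All settings reuse cells that gave the calls, so a kept direction is not independent support. Matching, thinning and the cluster left fewer cells and genes, and within cluster 7 the effect itself shrank: 95 of 127 genes kept their direction, with a median from 1.00 to 0.22. A cluster led by some of the called genes can give such a shrinkage by itself. Without the replicate block the count was 135, without the filter on low counts 223 (101 higher and 122 lower), and with CD8 cells taken by cluster 251 (122 higher and 129 lower). The last setting takes in cluster 8, in which 71 of 271 cells passed the CD8 gate. The 57 genes in CD4 cells became 148 without the replicate block, 18 with DESeq2 size factors, 91 without the filter, 0 against depth-matched cells and 1 in thinned cells. The 260 genes that differed between lineages became 148 with DESeq2 size factors and 98 with DESeq2, and 212 without the replicate block. For ENTPD1 in CD8 against CD4 cells, DESeq2 gave 2.92 on the log2 scale with adjusted p = 0.11, while the adjusted p lay between 6.1e-05 and 5.2e-04 in the edgeR alternatives. The 10 lists became 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.53 and 0.11), 7 against depth-matched cells (0 with an estimated correlation), 12 without TRBV19 cells (proliferation lost its call, adjusted p = 0.76; cytotoxic, tissue residency and natural killer genes gained one; 0 with an estimated correlation) and 10 without the replicate block (regulatory T lost its call, adjusted p = 0.067, and GZMK memory gained one, 0.031). In thinned cells the shares with an ENTPD1 UMI were 3.81% and 2.11%. The thinned CD8 gate held 46.0% of library 1, the CD4 gate 8.78% and 9.30%, and the regulatory gate 0.319% and 0.326%, since fewer UMIs per cell are left to pass a gate. Where a count moved otherwise, the cause was not tested.

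Signs turned for a few named genes. In thinned cells GZMK stood at -0.0128, CENPF at -0.29 and COX5A at -0.13 on the log2 scale, and without TRBV19 cells CCL5 at 0.0579. Within cluster 7 the values were -0.0414 for HMOX1, -0.0667 for RGS1, 0.18 for IL7R, -0.33 for GZMK, -0.0149 for CENPF, -0.000545 for OAS1 and -0.0416 for XCL1. Without replicate 1, XCL1 stood at -0.38, and without replicate 2 the differences between lineages for HMOX1 and ETS2 stood at 5.44 and 2.9998, with 0 UMIs of either gene in CD39-positive CD4 cells of library 1; without replicate 1 they stood at -10.65 and -6.18. The cause was not tested. Among 80 named or listed genes in CD8 cells, of which 50 were called, 40 lost their call with DESeq2, 37 of them because it gave no adjusted p, and against depth-matched cells 37 of the 64 still testable did. Leaving out a library left values without a test: without replicate 1, 43 of the 80 moved by more than their SE (GZMK from 0.55 to 0.29) and XCL1 reversed, and without replicate 2, 19 moved (CCL5 from -0.62 to -0.39). CD39 by antibody counts and sums per hashtag were not run, since the matrices used hold gene expression rows only. The CD4 and regulatory results rest on 4 and 2 ENTPD1 UMIs.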

Other observations

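The shares by receptor segment below were examined only after TRBV19 and TRAV13-2 had been seen among the called genes, and they fall outside the rule for named genes.

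Shares of T cell receptor segments differed between CD39-positive and CD39-negative CD8 T cells. TRBV19 and TRAV13-2, V segments of the beta and alpha chain, were the 2 called segments that were higher, while 18 others were lower. A TRBV19 UMI was found in 24 of 53 CD39-positive CD8 cells of library 1 (45.3%, Wilson interval 32.7 to 58.5) against 74 of 587 negative cells (12.6%, 10.2 to 15.5). In library 2 it was found in 7 of 17 (41.2%, 21.6 to 64.0) against 49 of 348 (14.1%, 10.8 to 18.1). TRAV13-2 was found in 73.5% and 67.9% of CD8 cells with TRBV19, against 4.06% and 3.56% of the others. Of CD8 cells with TRBV19, 70.4% and 69.6% lay in cluster 7, which was built without receptor segments, and they made up 60% and 61.9% of its CD8 cells. TRBV19 cells were 15.3% of CD8 cells in either library. Such like shares would also be found if both libraries were drawn from 1 pool of cells, which was not tested. Agreement between the 2 libraries may therefore be technical.

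Within cluster 7 the segment went with CD39 less clearly. TRBV19 was found in 21 of 31 positive (67.7%, 50.1 to 81.4) and 48 of 84 negative cells (57.1%, 46.5 to 67.2) of library 1, and in 4 of 6 (66.7%, 30.0 to 90.3) and 35 of 57 (61.4%, 48.4 to 72.9) of library 2. These intervals overlap. A hypothesis is that 1 expanded clone, pairing TRAV13-2 with TRBV19, carries much of the CD39-positive class. Without cells with TRBV19, 85 genes were called, 23 higher and 62 lower, and 35 of them were among the 182, so how much of the difference it carries stays open. Detection of both segments in the same cell was counted, but assembled receptor chains and clonotype calls were not analysed here.

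Across the 100 splits of CD8 cells by other genes, 3 raised the activation and MHC class II list as far as the ENTPD1 split (median log2 fold change 1.17), and 2 lowered the naive, memory and recirculation list as far (-0.57). The numbers were 5 for circulating effector genes, 6 for checkpoint and exhaustion genes, 11 for interferon response, 28 for follicular helper, 28 for regulatory T, 4 for the myeloid gene AIF1 and 59 for proliferation genes.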
